A study of Mus musculus with 12 samples.

How the data were processed

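RNA from CD11b+ cells sorted by flow cytometry from the hippocampus was measured in 12 mice, 3 in each of 4 groups: sham and irradiated animals of the strains C57BL/6 and Balb/c, per the labels. Each array holds 1 mouse, since the labels' protocols give the cell number per animal, 5000 to 10000 cells, with an RNA integrity number above 7.4, and 2 rounds of linear amplification before biotin labelling. The mice were 6.5 weeks old at treatment and 10.5 weeks old at analysis, 1 month later. The authors deposited log2 values of 45101 probe sets, made with GCRMA per the submitters' processing notes, which give no version. The values ran from 2.23 to 16.2, and all 12 arrays had the same sorted values within a tolerance of 0.001. No scanner files were used here, so another background correction was not tried, apart from a floor. The number of arrays limits the precision.

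Of the probe sets, 64 were controls, 34945 had 1 gene symbol in the given annotation, 932 had several and 9160 none, and none was named from a probe set with several. Symbols of 34741 probe sets were updated through the Entrez identifier. The 18193 genes were each represented by the probe set with the highest mean over all arrays, and 3425 of the tested genes had several kept probe sets, whose disagreement is given for the strain comparison. Probe sets above 5 on the log2 scale in at least 3 arrays were kept, which left 9120 genes. Eda2r and Itgax, which were to be named whatever they showed, fell below this filter and have no values.

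Log2 values were fitted in limma 3.58.1 (R 4.3.3) with lmFit and eBayes, with 1 mean per group and 8 residual degrees of freedom, and p-values were adjusted by Benjamini and Hochberg over the genes of each contrast. A call needs an adjusted p under 0.05. The contrasts were irradiated against sham in each strain, their average, their difference (the interaction) and Balb/c against C57BL/6 in sham mice. The 25 gene lists, with 481 genes in all, were tested with camera at a preset inter-gene correlation of 0.01. They cover microglial identity, activated microglia, p53 targets, cell cycle, type I interferon, MHC class I and II, inflammatory cytokines, complement and Fc receptors, lysosome, cholesterol and lipid handling, oxidative stress, oxidative phosphorylation and immediate early genes. They also cover markers of monocytes, border-associated macrophages, neutrophils, T and NK cells, B cells, erythroid cells, neurons, immature neurons and progenitors, oligodendrocytes, astrocytes and endothelial cells and pericytes. Adjustment was over the 22 lists with at least 4 tested members. Only members that passed the filter were tested, such as 17 of 37 on the array for cell cycle and 4 of 11 for neutrophils. High values in 1 group of 3 arrays are enough to pass it. An estimated correlation and fry, which tests whether a list moves on balance one way, were alternatives.

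The design, the lists, the alternatives and the rule for naming genes were fixed before the data were examined. For each contrast the rule took the 10 genes with the largest rise and the 10 with the largest fall among those called and whose arrays did not overlap between groups (for the average, in both strains), a separation that chance gives for 10% of genes with 3 against 3 arrays. For the interaction it took the 5 with the smallest p in each direction where fewer than 5 passed, and up to 4 members of each list by smallest p. A fixed set of microglial, radiation and strain marker genes was named whatever it showed. The alternatives were no filter or a filter at 7, quantile normalization or centring of arrays, a floor at 4, the mean of all probe sets of a gene or all probe sets as they are, eBayes with trend and robust, array weights, a fit of the compared groups alone, the replicate number as a block, other thresholds, the 3' minus 5' difference of Actb and Gapdh as a covariate and leaving out each array in turn. Leaving out 2 arrays that stood apart and the 18S signal as a covariate were added after the data were seen.

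The test was tried on simulated data with 200 changed genes among 9120, in 20 simulations per contrast. Of genes changed 2-fold it recovered 63.7% in C57BL/6, 66.0% in Balb/c, 85.8% in the average, 31.3% in the interaction and 65.3% between strains, and of genes changed 4-fold 92.7%, 93.2%, 97.3%, 82.5% and 93.3%. The simulated values were normal and independent between genes, without a bottom of the scale or arrays that stand apart. Recovery in the real data can therefore differ. Single values per array were compared by exact permutation within strains over 400 permutations, two-sided. Other splits of the arrays were refitted, all 10 for comparisons of 3 against 3 and 100 drawn of 200 for the average and the interaction, the latter also on values with the additive effects of strain and irradiation taken out.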

Results

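Microglia, the resident macrophages of the brain, were profiled 1 month after a dose of 10 Gy of X-rays to a 1 cm field over the forebrain, or after sham treatment. The cells were sorted as CD11b+ cells from the hippocampus of female C57BL/6 and Balb/c mice aged 10.5 weeks, and each of the 12 Affymetrix arrays held RNA from 1 mouse. The 4 groups had 3 arrays each, so the number of arrays limits the precision. The comparisons ask what irradiation does to the transcriptome of these CD11b+ cells and whether it does so alike in both strains. The sort can hold other cells beside microglia, and their share was not measured, so a change may lie in them. All arrays had a median log2 value of 2.44, with 35.3% of probe sets above 5.

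P2ry12, a purine receptor that marks resting microglia, was bright in every group and had a mean log2 value of 13.94 ± 0.16 (SD, n = 3) in C57BL/6 sham and 13.96 ± 0.21 in C57BL/6 irradiated arrays. In Balb/c its values were 14.18 ± 0.15 in sham and 14.06 ± 0.10 in irradiated arrays. H2-Ea, which C57BL/6 mice do not make, checks the strain labels and was higher in Balb/c sham by 2.11 ± 0.53 (log2 ± SE, adjusted p = 0.0274). Nnt, partly deleted in C57BL/6J, was higher by 1.43 ± 0.13 (adjusted p = 4.76e-05). H2-Ea lost its call without each of 4 arrays in turn, at adjusted p up to 0.105 without Balb/c sham replicate 1. The first principal component held 36.2% of the variance and separated the strains, and the second held 26.9% and separated sham from irradiated arrays.

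RNA quality differed between arrays. The excess of 3' over 5' signal of Actb and Gapdh, a sign of shortened RNA products, was 3.64 ± 0.13 (log2, SD, n = 3) in C57BL/6 sham and 3.63 ± 0.12 in C57BL/6 irradiated arrays. It was 3.69 ± 0.14 in Balb/c sham and 4.25 ± 0.56 in Balb/c irradiated arrays, where replicate 2 stood at 4.82. The mean difference between irradiated and sham arrays was 0.269 (exact permutation test within strains, two-sided, p = 0.215). The 18S ribosomal RNA control signal was lower after irradiation, with a log2 difference of -0.74 (the same exact permutation test, p = 0.005, the smallest that the 400 permutations can give). It was lower in every irradiated array than in every sham array, so its covariate cannot tell this signal apart from irradiation. C57BL/6 irradiated replicate 3 had the lowest mean correlation with the other arrays of its group, 0.966, close to the 0.968 of replicate 2. With Balb/c irradiated replicate 2, picked for its 3' minus 5' difference, it is 1 of the 2 arrays that stood apart. On the second principal component it lay furthest from the sham arrays, at -41.5, and C57BL/6 irradiated replicate 2 lay at 0.44. Leaving it out thus also removes the array with the largest shift on that component.

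The first comparison asked what irradiation changed in the CD11b+ cells of C57BL/6 mice. Cdkn1a, the p53-induced inhibitor of cyclin-dependent kinases, rose 20.4-fold, from 7.84 ± 0.47 to 12.19 ± 0.15 (log2 mean ± SD, n = 3, adjusted p = 3.90e-06). The proliferation marker Mki67 rose by 2.94 ± 0.26 (log2 ± SE, adjusted p = 5.28e-04), from 6.09 ± 0.33 to 9.03 ± 0.22. The cell cycle list rose with it and had a median change of 1.47 (adjusted p = 1.07e-12, and adjusted p = 0.0353 with an estimated correlation). Of its 17 members 8 were called higher, 13 adjusted over the list alone, and none was called lower. Among them were Cdk1, the mitotic kinase, at 2.10 ± 0.23, Cenpa, the centromeric histone, at 1.76 ± 0.19, and Top2a, a DNA topoisomerase, at 1.70 ± 0.21. The p53 targets rose and had a median change of 0.55 (adjusted p = 9.90e-08, and adjusted p = 0.00539 with an estimated correlation). In that list 7 of 22 were called higher, 11 adjusted over the list alone, and none lower, with 1.40 ± 0.11 for Ccng1, 1.36 ± 0.16 for Trp53inp1 and 0.98 ± 0.10 for Rps27l.

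Interferon-induced genes rose in C57BL/6, 13 of 24 called higher, 17 adjusted over the list alone, and none lower. This list had a median change of 1.32 (adjusted p = 6.79e-12, and adjusted p = 0.0314 with an estimated correlation). Oasl2, an oligoadenylate synthetase-like protein, rose by 2.71 ± 0.17 from values near the bottom of the scale. Usp18, which removes ISG15 from proteins, rose by 2.23 ± 0.39 and Ifitm3, an antiviral membrane protein, by 1.25 ± 0.22. The chemokines Cxcl9 and Cxcl10 rose by 3.27 ± 0.73 and 2.97 ± 0.42. Of the activated microglia genes 6 of 24 were called higher and 0 lower, 10 higher and 1 lower adjusted over the list alone, with 2.66 ± 0.46 for Axl, 2.61 ± 0.27 for Cst7, 2.32 ± 0.32 for Lgals3 and 1.15 ± 0.18 for Cd52. That list had a median change of 0.50 (adjusted p = 7.78e-07, and adjusted p = 0.235 with an estimated correlation). Of the MHC class II genes, whose products present peptides to T cells, 3 of 9 were called higher, 5 adjusted over the list alone, with 2.38 ± 0.49 for H2-Aa, 2.79 ± 0.60 for H2-Ab1 and 2.48 ± 0.56 for Cd74. The class II list had a median change of 0.53 (adjusted p = 4.03e-04, and adjusted p = 0.235 with an estimated correlation). Usp18 lost its call without C57BL/6 irradiated replicate 3 (adjusted p = 0.0543), and Ifitm3 did so without C57BL/6 irradiated replicate 3 (adjusted p = 0.0701). H2-Aa did so without each of 3 arrays in turn, at adjusted p up to 0.112 without C57BL/6 irradiated replicate 3, and H2-Ab1 did so without each of 5 arrays in turn, at adjusted p up to 0.129 without C57BL/6 irradiated replicate 3. Cd74 did so without each of 8 arrays in turn, at adjusted p up to 0.147 without C57BL/6 irradiated replicate 3.

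Microglial identity genes were lower as a list in C57BL/6, with none of 22 members called. The list had a median change of -0.19 (adjusted p = 0.0142, and adjusted p = 0.34 with an estimated correlation). P2ry12, Tmem119 and Cx3cr1 did not pass, at 0.02 ± 0.14, -0.19 ± 0.10 and -0.22 ± 0.11. Lists of markers of other cells were higher, at a 3' minus 5' difference of 3.63 ± 0.12 against 3.64 ± 0.13 in sham arrays and an 18S signal of 11.69 ± 0.12 against 12.16 ± 0.13 (SD, n = 3). Of the monocyte markers 5 of 11 were called, 7 adjusted over the list alone, with 2.52 ± 0.42 for Ccr2, 2.38 ± 0.33 for Cd44 and 1.14 ± 0.18 for Fn1. They had a median change of 1.13 (adjusted p = 1.53e-07, and adjusted p = 0.0546 with an estimated correlation). Astrocyte markers, 1 of 12 called, had a median change of 0.73 (adjusted p = 1.29e-05, and adjusted p = 0.273 with an estimated correlation). Border-associated macrophage markers, 1 of 13 called, had a median change of 0.68 (adjusted p = 1.02e-04, and adjusted p = 0.306 with an estimated correlation). Endothelial and pericyte markers, 0 of 10 called, had a median change of 0.49 (adjusted p = 0.00374, and adjusted p = 0.306 with an estimated correlation). Leaving out 1 array ended the call of the endothelial list (without C57BL/6 irradiated replicate 2 adjusted p = 0.0925) and of the microglial identity list (without C57BL/6 irradiated replicate 1 adjusted p = 0.0579). Endothelial markers had a median of 0.32 without C57BL/6 irradiated replicate 2. Border-associated macrophage markers had a median of 0.44 without C57BL/6 sham replicate 2.

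Some metabolic and immune lists passed in C57BL/6 with few or no single genes called, and none of them held with an estimated correlation. Cholesterol and lipid handling, 3 of 18 called higher and 0 lower, had a median change of 0.52 (adjusted p = 1.02e-04, and adjusted p = 0.0506 with an estimated correlation). Apoe, a lipid carrier, rose by 1.28 ± 0.29, and Ch25h, which makes 25-hydroxycholesterol, by 2.79 ± 0.56. Oxidative phosphorylation, 0 of 29 called, had a median change of 0.25 (adjusted p = 1.34e-05, and adjusted p = 0.306 with an estimated correlation). The MHC class I pathway, 0 of 9 called, had a median change of 0.25 (adjusted p = 0.0115, and adjusted p = 0.306 with an estimated correlation). Complement and Fc receptors, 0 of 13 called, had a median change of 0.16 (adjusted p = 0.0115, and adjusted p = 0.305 with an estimated correlation). The lysosome list, 0 of 26 called, had a median change of 0.08 (adjusted p = 0.0212, and adjusted p = 0.346 with an estimated correlation). Inflammatory cytokines, 4 of 24 called higher and 1 lower, and 8 higher and 5 lower adjusted over the list alone, had a median change of 0.45 (adjusted p = 0.0282, and adjusted p = 0.346 with an estimated correlation). Immediate early and heat shock genes were lower, with Junb at -0.96 ± 0.21 as the 1 of 21 called and 7 lower adjusted over the list alone. Their list had a median change of -0.48 (adjusted p = 4.40e-05, and adjusted p = 0.306 with an estimated correlation). The inflammatory list lost its call without C57BL/6 sham replicates 2 and 3 and irradiated replicate 1 (adjusted p up to 0.134, without C57BL/6 irradiated replicate 1), and the lysosome list without C57BL/6 sham replicate 2 and irradiated replicate 2 (adjusted p up to 0.161, without C57BL/6 irradiated replicate 2) and with the mean of all probe sets of a gene (adjusted p = 0.116). The complement list lost its call with a filter at 7 (adjusted p = 0.0664). Apoe lost its call without each of 9 arrays in turn, at adjusted p up to 0.142 without C57BL/6 irradiated replicate 3, and Ch25h did so without each of 5 arrays in turn, at adjusted p up to 0.0926 without C57BL/6 irradiated replicate 3. Junb did so without each of 8 arrays in turn, at adjusted p up to 0.142 without C57BL/6 irradiated replicate 3. MHC class I had a median of 0.15 without C57BL/6 irradiated replicate 3. Complement had a median of 0.09 without C57BL/6 sham replicate 2. Lysosome had a median of 0.04 without C57BL/6 irradiated replicate 2. Inflammatory cytokines had a median of 0.29 without C57BL/6 sham replicate 2 and 0.30 without C57BL/6 sham replicate 3. Immediate early genes had a median of -0.28 without C57BL/6 sham replicate 1 and -0.32 without C57BL/6 irradiated replicate 3. The lists that did not pass were oxidative stress, at a median of 0.08, neutrophils at 0.02, neurons at 0.50, immature neurons at 0.51 and oligodendrocytes at -0.24, with adjusted p from 0.0877 to 0.778. These medians depend on single arrays. When each array was left out in turn, that of neutrophils ran from -0.86 to 1.15, of neurons from 0.17 to 0.78, of oligodendrocytes from -0.40 to 0.04, of oxidative stress from -0.01 to 0.16 and of immature neurons from 0.39 to 0.61. The immature neuron list was called under 3 alternatives (adjusted p down to 0.0199 without C57BL/6 irradiated replicate 2) and the oligodendrocyte list, as lower, under 2 alternatives (adjusted p down to 0.00161 without C57BL/6 irradiated replicate 1).

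In all, 335 of 9120 genes were called in C57BL/6, 202 higher and 133 lower, and 1945 had an unadjusted p under 0.05 where chance gives 456. With a change of at least 2-fold, 148 were higher and 31 lower. The largest rises beside Cdkn1a, Cxcl9, Cxcl10 and Mki67 were D630023F18Rik (4.46), Cd244a (3.48), Cd72 (3.45), Rrm2 (3.45), Plbd1 (3.26) and Nusap1 (7.99-fold), with adjusted p from 3.90e-06 to 0.0384 for these 10. Sham values of D630023F18Rik were 2.23 ± 0.00, the bottom of the scale, so its size depends on the background correction. For 6 of the 20 genes named in this paragraph as the largest changes the lower group mean was under 5, so their sizes are rough. The largest falls were Ptger3 (-2.10), Tnfrsf17 (-1.75), Liph (-1.71), Lag3 (-1.69), Ermap (-1.55), Lrrc75a (-1.34), Acin1 (-1.32), Thoc3 (-1.32), 4930447M23Rik (-1.32) and Mrm1 (-1.29), with adjusted p from 0.00263 to 0.0424. All 3 irradiated arrays lay on one side of all 3 sham arrays for each of these 20 genes, as the rule for naming required. Ptger3 encodes a prostaglandin E2 receptor, Lag3 an inhibitory receptor that binds MHC class II, and Tnfrsf17 the receptor BCMA. Cxcl9 lost its call without each of 8 arrays in turn, at adjusted p up to 0.13 without C57BL/6 irradiated replicate 3, and Plbd1 did so without each of 2 arrays in turn, at adjusted p up to 0.0732 without C57BL/6 irradiated replicate 3. Nusap1 did so without each of 2 arrays in turn, at adjusted p up to 0.0908 without C57BL/6 irradiated replicate 3, and Ptger3 did so without C57BL/6 irradiated replicate 3 (adjusted p = 0.0608). Liph did so without each of 8 arrays in turn, at adjusted p up to 0.101 without C57BL/6 sham replicate 1, and Lag3 did so without C57BL/6 irradiated replicate 3 (adjusted p = 0.0714). Acin1 did so without each of 8 arrays in turn, at adjusted p up to 0.118 without C57BL/6 irradiated replicate 3, and 4930447M23Rik did so without each of 9 arrays in turn, at adjusted p up to 0.158 without C57BL/6 irradiated replicate 3. Mrm1 did so without each of 4 arrays in turn, at adjusted p up to 0.0679 without C57BL/6 sham replicate 2. The count was 207 without C57BL/6 sham replicate 1, 163 without C57BL/6 sham replicate 2, 214 without C57BL/6 irradiated replicate 1 and 113 without C57BL/6 irradiated replicate 3. It was 155 with no filter on dim probe sets, 96 from a fit of the 6 arrays alone and 104 without the 2 arrays that stood apart, C57BL/6 irradiated replicate 3 and Balb/c irradiated replicate 2. With the 18S signal as a covariate 16 of the 20 were called, and 19 with the 3' minus 5' difference.

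**Figure D1:**
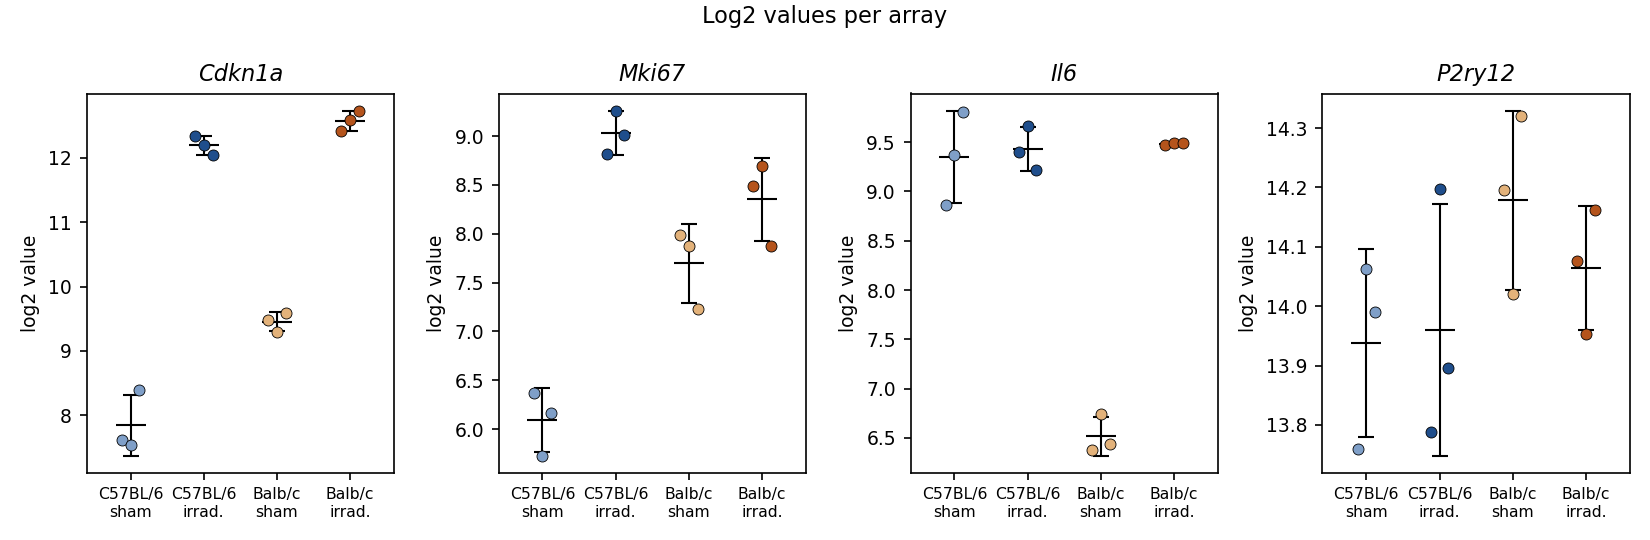
Log2 values of Cdkn1a, Mki67, Il6 and P2ry12 in each array by group, with the mean and SD of 3 arrays. Cdkn1a is higher in every irradiated array than in any sham array, and Il6 is low in Balb/c sham arrays at 6.52 ± 0.20.

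The same question was put to Balb/c mice. Cdkn1a rose 8.69-fold, from 9.46 ± 0.15 to 12.57 ± 0.16 (log2 mean ± SD, n = 3, adjusted p = 4.55e-05). The cytokine Il6 rose by 2.97 ± 0.21 (log2 ± SE, adjusted p = 4.64e-05) and the chemokine Ccl5 by 4.19 ± 0.71 (adjusted p = 0.00862). Interferon-induced genes rose, 14 of 24 called higher, 20 adjusted over the list alone, and none lower. That list had a median change of 1.27 (adjusted p = 1.50e-18, and adjusted p = 0.00728 with an estimated correlation). Among them were Ifi204, a DNA sensor, at 3.14 ± 0.44, Ifit3 at 2.54 ± 0.32, Usp18 at 2.77 ± 0.39 and Rtp4 at 1.97 ± 0.23. Of the p53 targets 11 of 22 were called higher and 0 lower, 11 higher and 3 lower adjusted over the list alone, with 1.65 ± 0.11 for Ccng1, 1.41 ± 0.16 for Trp53inp1 and 0.98 ± 0.10 for Rps27l. Their list had a median change of 0.73 (adjusted p = 2.79e-08, and adjusted p = 0.00388 with an estimated correlation). In the cell cycle list 0 of 17 members were called higher and 1 lower, Mcm5, a subunit of the replicative helicase, at -0.95 ± 0.14. That list did not pass, with a median of 0.17 (from -0.07 to 0.30 when each array was left out in turn) and a mean of 0.01 (adjusted p = 0.993), and Mki67 was at 0.66 ± 0.26 (adjusted p = 0.168).

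Beside the interferon list, 3 immune lists passed in Balb/c at the preset correlation, and none of these 3 held with an estimated one. Of the inflammatory cytokine genes 4 of 24 were called higher and 2 lower, 5 higher and 3 lower adjusted over the list alone, with 2.17 ± 0.18 for Ccl12 and 2.11 ± 0.42 for Cxcl10 beside Il6 and Ccl5. The list had a median change of 0.12 (adjusted p = 0.0343, and adjusted p = 0.467 with an estimated correlation). MHC class II genes, 1 of 9 called, had a median change of 0.91 (adjusted p = 0.0397, and adjusted p = 0.467 with an estimated correlation). Activated microglia genes, 3 of 24 called higher and 1 lower, had a median change of 0.03 (adjusted p = 0.0436, and adjusted p = 0.609 with an estimated correlation). MHC class I and complement did not pass, at medians of -0.19 (adjusted p = 0.662) and 0.05 (adjusted p = 0.192). Cst7 rose by 2.96 ± 0.27 and Trem2, a lipid receptor, fell, at -1.02 ± 0.20. Cholesterol and lipid genes, 2 of 18 called higher and 0 lower, and 3 higher and 1 lower adjusted over the list alone, had a median change of 0.30 (adjusted p = 0.00476, and adjusted p = 0.204 with an estimated correlation). Immediate early genes were lower, 5 of 21 called, with -1.16 ± 0.21 for Junb, -0.97 ± 0.17 for Rgs1 and -0.70 ± 0.12 for Zfp36. Their list had a median change of -0.38 (adjusted p = 1.93e-05, and adjusted p = 0.397 with an estimated correlation). Microglial identity genes did not pass as a list (median -0.10, and from -0.13 to -0.05 without single arrays, adjusted p = 0.196), though Crybb1 and Bin1 fell, at -1.30 ± 0.19 and -1.07 ± 0.19. The activated microglia list lost its call without C57BL/6 sham replicate 1, Balb/c sham replicates 2 and 3 and Balb/c irradiated replicates 1 and 3 (adjusted p up to 0.332, without Balb/c irradiated replicate 1). MHC class II lost it without Balb/c sham replicate 2 and irradiated replicate 1 (adjusted p up to 0.146, without Balb/c sham replicate 2), and inflammatory cytokines without Balb/c sham replicate 1 and irradiated replicate 1 (adjusted p up to 0.142, without Balb/c irradiated replicate 1). After quantile normalization of the tested genes the adjusted p of the MHC class II and activated microglia lists was 0.0502 each. MHC class II also lost its call with no filter (adjusted p = 0.0601), and activated microglia with a filter at 7 (adjusted p = 0.0798) and in a fit of the 6 arrays alone (adjusted p = 0.0504). The inflammatory list also lost its call with the 18S covariate (adjusted p = 0.0566). MHC class II came to a median of 0.60 without Balb/c sham replicate 2 and 0.58 without Balb/c irradiated replicate 1. Activated microglia genes came to a median of 0.12 without Balb/c sham replicate 1, 0.003 without Balb/c sham replicate 3, -0.06 without Balb/c irradiated replicate 1 and 0.18 without Balb/c irradiated replicate 2. Inflammatory cytokines came to a median of 0.19 without Balb/c irradiated replicate 2 and 0.24 without Balb/c irradiated replicate 3. Cholesterol and lipid genes came to a median of 0.18 without Balb/c irradiated replicate 3. Cxcl10 lost its call without each of 2 arrays in turn, at adjusted p up to 0.0635 without Balb/c sham replicate 2, and Trem2 did so without Balb/c sham replicate 2 (adjusted p = 0.0673).

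Some lists of markers of other cells rose in Balb/c, in the group with the highest 3' minus 5' difference, 4.25 ± 0.56, and the lowest 18S signal, 11.19 ± 0.61 against 12.19 ± 0.22 in sham arrays (SD, n = 3). S100a8 and S100a9, the calprotectin subunits of neutrophils, rose by 4.10 ± 0.67 and 3.19 ± 0.64, and Camp and Ngp did not pass, at 2.99 ± 1.55 and 3.54 ± 1.68. The neutrophil list had a median change of 3.36 (adjusted p = 7.81e-04, and adjusted p = 0.267 with an estimated correlation). Only 4 of its 11 markers on the array passed the filter, which high values in 1 group of 3 arrays alone can meet. Monocyte markers, 4 of 11 called, had a median change of 0.89 (adjusted p = 1.28e-04, and adjusted p = 0.204 with an estimated correlation). Border-associated macrophage markers, 2 of 13 called, had a median change of 0.47 (adjusted p = 7.11e-05, and adjusted p = 0.397 with an estimated correlation). Of the astrocyte markers 5 of 12 were called, with 1.59 ± 0.38 for Gfap, 1.28 ± 0.32 for Aqp4 and 0.95 ± 0.21 for Gja1. Astrocyte genes as a list had a median change of 0.96 (adjusted p = 3.45e-08, and adjusted p = 0.204 with an estimated correlation). Pdgfrb, a pericyte receptor, rose by 0.99 ± 0.18, and Vtn by 1.28 ± 0.29. Endothelial and pericyte markers had a median change of 0.92 (adjusted p = 1.87e-05, and adjusted p = 0.257 with an estimated correlation). The neutrophil list lost its call with the 18S covariate (adjusted p = 0.0566). Border-associated macrophage markers came to a median of 0.84 without Balb/c irradiated replicate 2. S100a9 lost its call without each of 2 arrays in turn, at adjusted p up to 0.067 without Balb/c sham replicate 1, and Gfap did so without each of 4 arrays in turn, at adjusted p up to 0.121 without Balb/c sham replicate 1. Aqp4 did so without each of 6 arrays in turn, at adjusted p up to 0.131 without Balb/c sham replicate 1, and Gja1 did so without each of 4 arrays in turn, at adjusted p up to 0.101 without Balb/c sham replicate 1. Vtn did so without each of 3 arrays in turn, at adjusted p up to 0.11 without Balb/c sham replicate 2.

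Beside cell cycle and microglial identity, 8 lists did not pass in Balb/c. Neuron markers, 0 of 8 called, had a median of 0.04 (adjusted p = 0.906), oligodendrocyte markers, 0 of 11 called, of 0.06 (adjusted p = 0.792) and immature neuron markers, 0 of 4 called, of 0.51 (adjusted p = 0.106). Oxidative phosphorylation was at 0.08 (adjusted p = 0.126), lysosome at -0.07 (adjusted p = 0.311) and oxidative stress at -0.09 (adjusted p = 0.833), beside MHC class I and complement. When each array was left out in turn, the median ran from -0.28 to 0.18 for neurons, from -0.07 to 0.18 for oligodendrocytes, from 0.35 to 0.79 for immature neurons and from -0.02 to 0.14 for oxidative phosphorylation. It ran from -0.11 to -0.03 for lysosome, from -0.11 to 0.03 for oxidative stress, from -0.29 to -0.01 for MHC class I and from -0.02 to 0.10 for complement. Complement was called under 4 alternatives (adjusted p down to 0.00219 with the 18S covariate), immature neurons under 5 alternatives (down to 0.0211 without both arrays that stood apart) and oxidative phosphorylation under 5 alternatives (down to 2.61e-04 with the 18S covariate).

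In all, 561 genes were called in Balb/c, 297 higher and 264 lower, and 2082 had an unadjusted p under 0.05. With at least a 2-fold change, 188 were higher and 61 lower. The largest rises beside Cdkn1a, Il6, Ccl5 and Ifi204 were S100a8 (4.10), Ch25h (3.86), Ccl8 (3.66), S100a9 (3.19), Ly6e (7.98-fold) and Ifit1 (2.99), with adjusted p from 4.55e-05 to 0.0171 for these 10. The largest falls were Ptger3 (-4.05), Lag3 (-2.34), Itgb3 (-2.28), Duoxa1 (-2.26), Gp9 (-2.09), Rcc2 (-1.71), Tnfrsf17 (-1.67), Amz1 (-1.63), Col6a3 (-1.57) and Atf3 (-1.54), with adjusted p from 8.73e-05 to 0.041. For these 20 genes the irradiated and sham arrays did not overlap, as the rule for naming required. For 9 of the 20 the lower group mean was under 5, so their sizes are rough. Itgb3 encodes an integrin and Atf3 a stress-induced transcription factor. Itgb3 lost its call without each of 2 arrays in turn, at adjusted p up to 0.0565 without Balb/c sham replicate 2, and Amz1 did so without each of 5 arrays in turn, at adjusted p up to 0.106 without Balb/c irradiated replicate 3. Col6a3 did so without Balb/c sham replicate 2 (adjusted p = 0.0542), and Atf3 did so without each of 7 arrays in turn, at adjusted p up to 0.129 without Balb/c irradiated replicate 3. The count of genes was 268 without Balb/c sham replicate 1, 218 without Balb/c sham replicate 2, 337 without Balb/c irradiated replicate 2 and 280 without Balb/c irradiated replicate 3. It was 283 with no filter on dim probe sets, 364 from a fit of the 6 arrays alone, 104 with the 3' minus 5' difference as a covariate, 39 with the 18S signal as a covariate and 361 without the 2 arrays that stood apart. Of the 20 genes 10 were called with the 3' minus 5' covariate and 6 with the 18S covariate. Cdkn1a and Il6 were called with both. Since the 18S signal was lower in every irradiated array than in every sham array, calls lost with its covariate cannot decide on that signal.

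Averaged over both strains, irradiation raised p53 targets, 12 of 22 called higher and 1 lower, 13 higher and 2 lower adjusted over the list alone. They had a median change of 0.69 (adjusted p = 4.17e-08, and adjusted p = 0.00419 with an estimated correlation). Interferon-induced genes rose too, 17 of 24 called higher and 0 lower, 17 adjusted over the list alone. Those had a median change of 1.46 (adjusted p = 6.24e-17, and adjusted p = 0.00979 with an estimated correlation). Cdkn1a rose by 3.73 ± 0.15 (log2 ± SE, adjusted p = 5.01e-07), Ccng1 by 1.52 ± 0.08 and Usp18 by 2.50 ± 0.27. Of the activated microglia genes 6 of 24 were called higher and 1 lower, and Cst7, an inhibitor of lysosomal proteases, and Lgals3, a galectin, rose by 2.79 ± 0.19 and 1.77 ± 0.22. That list had a median change of 0.25 (adjusted p = 7.68e-05, and adjusted p = 0.252 with an estimated correlation). Of the MHC class II genes 5 of 9 were called, with H2-Aa at 2.08 ± 0.34 and Cd74, the invariant chain, at 2.07 ± 0.40. MHC class II as a list had a median change of 0.72 (adjusted p = 0.00183, and adjusted p = 0.252 with an estimated correlation). Mdm2, which degrades p53, rose by 0.74 ± 0.14, Axl by 1.94 ± 0.32, Ccr2 by 1.85 ± 0.30 and Tnf by 1.12 ± 0.29. Tnf lost its call without each of 3 arrays in turn, at adjusted p up to 0.0593 without Balb/c sham replicate 1. Clec7a, Il1b, Cd68 and Apoe did not pass, at 0.48 ± 0.15, 0.95 ± 0.36, 0.30 ± 0.13 and 0.39 ± 0.20.

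Immediate early genes fell in the average, 11 of 21 called lower, with -0.95 ± 0.20 for Jun, -1.06 ± 0.15 for Junb and -1.09 ± 0.19 for Klf2. That list had a median change of -0.55 (adjusted p = 3.70e-06, and adjusted p = 0.252 with an estimated correlation). Of the microglial identity genes 4 of 22 were called lower and 1 higher, with Crybb1 at -0.90 ± 0.13 and Bin1 at -0.80 ± 0.13. Identity genes had a median change of -0.13 (adjusted p = 0.0351, and adjusted p = 0.405 with an estimated correlation). P2ry12, Tmem119 and Cx3cr1 did not pass, at -0.05 ± 0.10, -0.17 ± 0.07 and -0.16 ± 0.07. Cell cycle genes, 8 of 17 called, had a median change of 0.85 (adjusted p = 1.48e-05, and adjusted p = 0.179 with an estimated correlation). Inflammatory cytokines, 6 of 24 called higher and 4 lower, had a median change of 0.26 (adjusted p = 0.00836, and adjusted p = 0.301 with an estimated correlation). Complement and Fc receptors, 4 of 13 called higher and 1 lower, had a median change of 0.11 (adjusted p = 0.0254, and adjusted p = 0.286 with an estimated correlation). Cholesterol and lipid handling, 4 of 18 called higher and 1 lower, and 8 higher and 1 lower adjusted over the list alone, had a median change of 0.40 (adjusted p = 1.00e-04, and adjusted p = 0.0672 with an estimated correlation). Oxidative phosphorylation, 1 of 29 called higher and 1 lower, had a median change of 0.17 (adjusted p = 2.76e-04, and adjusted p = 0.389 with an estimated correlation). The identity list lost its call without C57BL/6 sham replicate 2, C57BL/6 irradiated replicates 1 and 3 and Balb/c irradiated replicate 1 (adjusted p up to 0.0677, without C57BL/6 irradiated replicate 1). With the 18S covariate it was at an adjusted p of 0.0958 and without both arrays that stood apart at 0.0761. The complement list lost it without Balb/c irradiated replicates 1 and 3 (adjusted p up to 0.0667, without Balb/c irradiated replicate 1), with a filter at 7 (adjusted p = 0.206) and with the mean of all probe sets (adjusted p = 0.108). Its median was 0.06 without C57BL/6 sham replicate 2 and 0.07 without Balb/c irradiated replicate 3.

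Lists of markers of other cells passed in the average of both strains, beside the 3' minus 5' difference of 4.25 ± 0.56 in Balb/c irradiated arrays and the lower 18S signal of irradiated arrays in both strains. Monocyte markers, 7 of 11 called, had a median change of 0.88 (adjusted p = 7.54e-07, and adjusted p = 0.0876 with an estimated correlation). Border-associated macrophage markers, 7 of 13 called, had a median change of 0.60 (adjusted p = 1.48e-05, and adjusted p = 0.252 with an estimated correlation). Neutrophil markers, 2 of 4 called, had a median change of 1.76 (adjusted p = 0.018, and adjusted p = 0.306 with an estimated correlation). The neutrophil median was 3.36 in Balb/c and 0.02 in C57BL/6, where it ran from -0.86 to 1.15 when each array was left out in turn. The interaction of this list was not called with an estimated correlation (adjusted p = 0.528). The neutrophil score of irradiated against sham arrays did not pass (exact permutation test within strains, two-sided, p = 0.115). Astrocyte markers, 9 of 12 called and 11 adjusted over the list alone, had a median change of 0.78 (adjusted p = 5.70e-08, and adjusted p = 0.179 with an estimated correlation). Endothelial and pericyte markers, 5 of 10 called, had a median change of 0.72 (adjusted p = 3.83e-05, and adjusted p = 0.252 with an estimated correlation). Immature neuron and progenitor markers, 0 of 4 called, had a median change of 0.40 (adjusted p = 0.0363, and adjusted p = 0.252 with an estimated correlation). That last list lost its call without C57BL/6 sham replicates 1 and 3, C57BL/6 irradiated replicate 1, Balb/c sham replicate 2 and Balb/c irradiated replicates 1 and 3 (adjusted p up to 0.0689, without C57BL/6 irradiated replicate 1) and with no filter (adjusted p = 0.398). The neutrophil list lost it without both arrays that stood apart (adjusted p = 0.0899) and with the 18S covariate (adjusted p = 0.337).

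The lists that did not pass in the average were 5. Oxidative stress, 1 of 13 called higher and 2 lower, had a median of 0.11 (adjusted p = 0.523). In it Cybb, the catalytic subunit of the phagocyte NADPH oxidase, rose by 1.76 ± 0.25 and Ncf1, another subunit, fell, at -0.43 ± 0.06. Neuron markers had a median of 0.18 (adjusted p = 0.496). Oligodendrocyte markers had a median of -0.07 (adjusted p = 0.523). MHC class I had a median of -0.0012 and a mean of 0.16 (adjusted p = 0.32), and lysosome a median of -0.02 and a mean of 0.01 (adjusted p = 0.523). The median and the mean thus differed in sign for both. When each array was left out in turn, the median ran from 0.02 to 0.16 for oxidative stress, from -0.03 to 0.40 for neurons, from -0.19 to 0.02 for oligodendrocytes, from -0.05 to 0.07 for MHC class I and from -0.04 to 0.01 for lysosome. The lists of T and NK cells and of B cells had 2 tested members each and the erythroid list 0, too few for a list test. With the 18S covariate the MHC class I and lysosome lists were called (adjusted p = 0.0029 and adjusted p = 0.034), and MHC class I also with the 3' minus 5' covariate (adjusted p = 0.0137).

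In all, 1447 genes were called in the average, 704 higher and 743 lower, with 274 higher and 38 lower by at least 2-fold and 2888 at an unadjusted p under 0.05. The largest rises were Cdkn1a (3.73), Ccl5 (3.42), Ch25h (3.32), Cxcl9 (2.85), Cst7 (2.79), Plbd1 (2.79), Pqlc3 (2.72), Ifit1 (2.63), Ms4a4c (2.60) and Cd72 (2.55), with adjusted p from 5.01e-07 to 0.00585. The largest falls were Ptger3 (-3.07), Lag3 (-2.01), Tnfrsf17 (-1.71), Duoxa1 (-1.68), Gp9 (-1.54), Col6a3 (-1.41), Cebpa (-1.28), Lrrc75a (-1.28), Tnfrsf12a (-1.28) and Csmd3 (-1.25), with adjusted p from 4.83e-05 to 0.00601. In both strains the irradiated and sham arrays of these 20 genes did not overlap, as the rule for naming required. All 20 kept their calls without each array in turn. With the 3' minus 5' covariate 20 of them were called and with the 18S covariate 15. Gp9 is a platelet glycoprotein and Cebpa a myeloid transcription factor. The count was 925 without C57BL/6 irradiated replicate 3 and 923 without Balb/c sham replicate 2. It was 867 with no filter, 873 with the 3' minus 5' covariate, 241 with the 18S covariate and 788 without both arrays that stood apart. The drop with the 18S covariate cannot decide on that signal, which was lower in every irradiated array than in every sham array. Other splits of the arrays also gave list calls at the preset correlation, up to 13 in C57BL/6, 15 in Balb/c and 18 in the average. With an estimated correlation the p53 and interferon lists held in each of these comparisons, and the cell cycle list in C57BL/6.

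**Figure D2:**
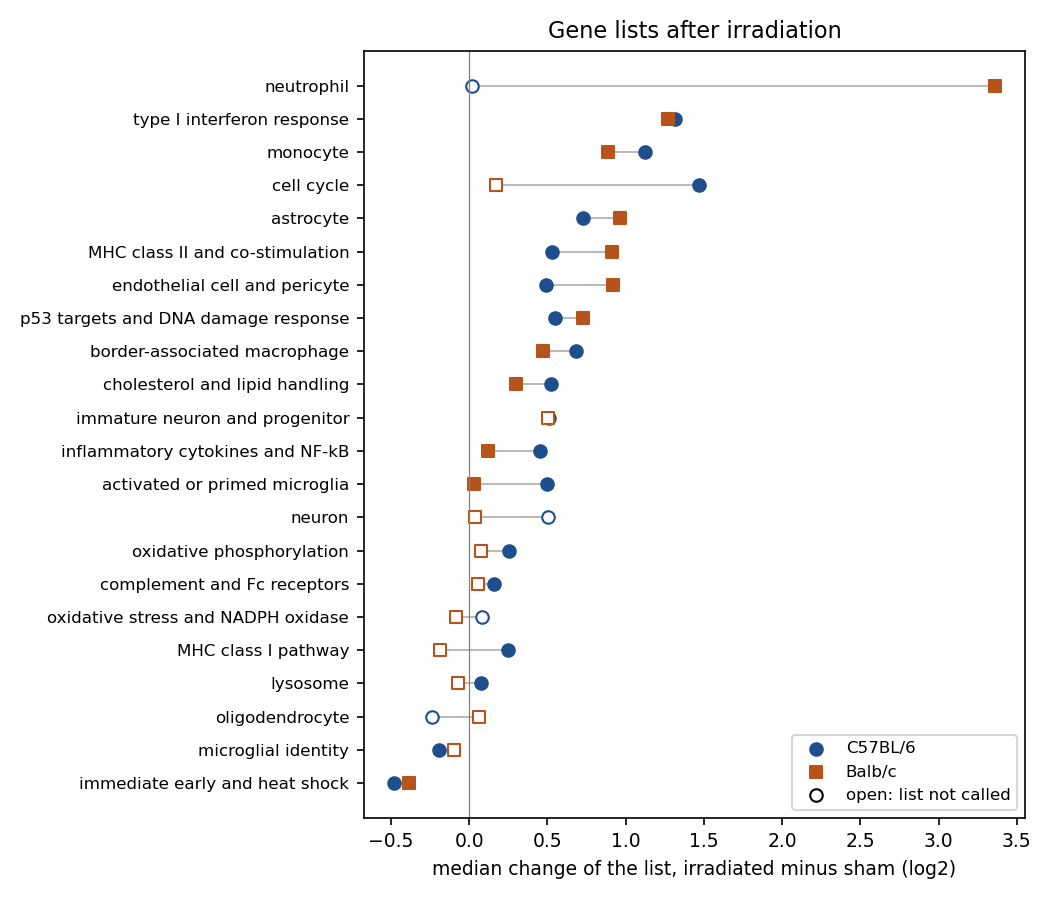
Median log2 change of the 22 tested lists in C57BL/6 (circles) and Balb/c (squares), open where the list did not pass. The cell cycle list stands at 1.47 in C57BL/6 and 0.17 in Balb/c, where it ran from -0.07 to 0.30 when each array was left out in turn.

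**Figure D3:**
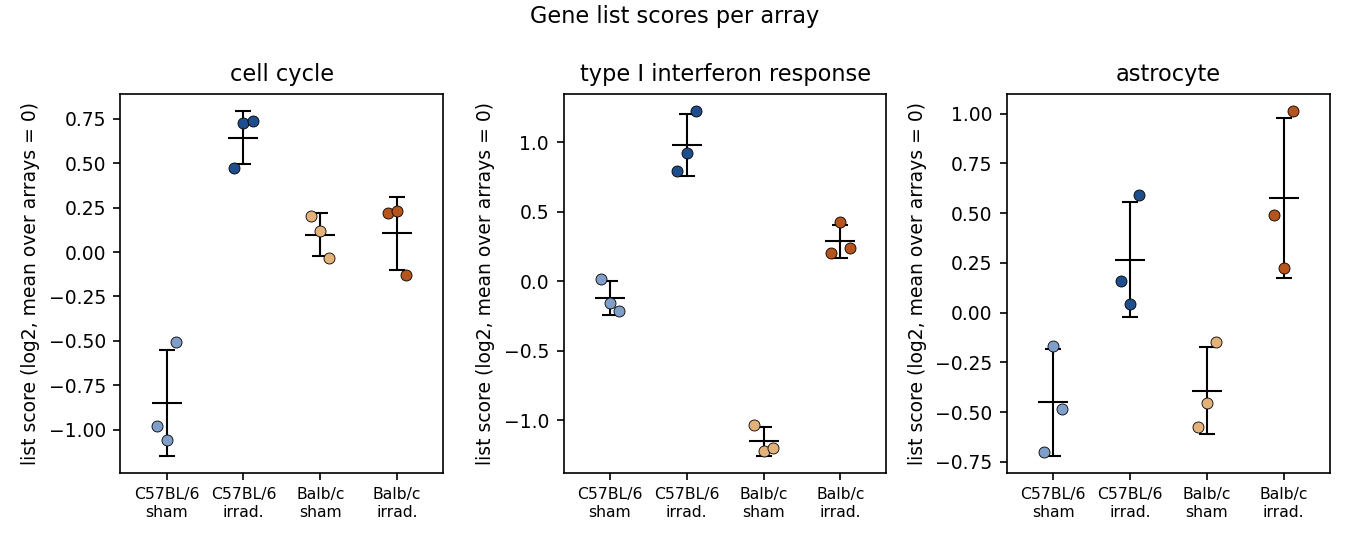
Scores of the cell cycle, type I interferon response and astrocyte lists in each array, as the mean log2 deviation of the members from their mean over all arrays, with the group mean and SD. The interferon score is -0.12 ± 0.12 in C57BL/6 sham and -1.15 ± 0.10 in Balb/c sham arrays.

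Most changes ran the same way in both strains. Of the genes called in C57BL/6, 92.2% had the same direction in Balb/c. Of those called in Balb/c, 95.4% had it in C57BL/6, against 68.1% of all genes. Called higher in both strains were 95 genes (6.58 from independent lists, Fisher's exact test p = 8.38e-91) and called lower in both were 53 (3.85, p = 9.50e-48). Among them were Cdkn1a, Ccng1, Ptger3, Lag3 and Tnfrsf17. Of the genes called in both strains only Mcm5 went in opposite directions, at 0.82 ± 0.14 in C57BL/6 and -0.95 ± 0.14 in Balb/c. Across genes the log2 changes of the strains correlated with r = 0.635 (Spearman's rho 0.502). These contrasts share no arrays, but both came from the same fit of all groups. Their calls therefore share the variance estimate of each gene and are not independent. The counts expected from independent lists and the Fisher p-values do not allow for this. Genes are also not independent replicates.

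**Figure D4:**
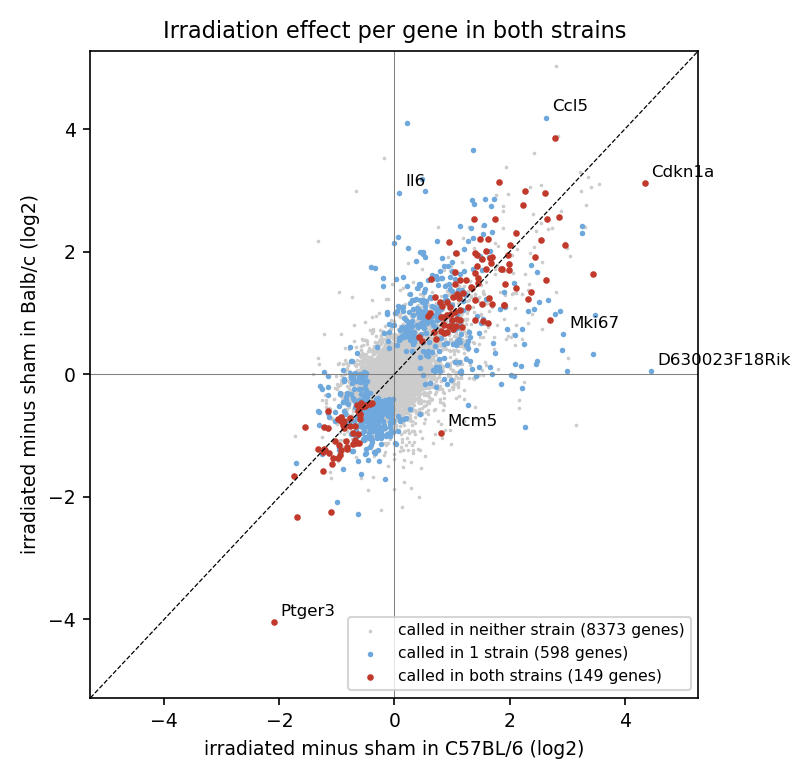
Log2 change after irradiation in C57BL/6 (x axis) and in Balb/c (y axis) for each tested gene, marked by whether it was called in neither strain, 1 strain or both, with the line of equal change dashed. Cdkn1a lies high in both strains, and Mki67, D630023F18Rik and Il6 lie off the line.

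Whether the strains responded differently was tested by the interaction, the change in Balb/c minus the change in C57BL/6. It called 7 genes, 4 higher and 3 lower, with 735 at an unadjusted p under 0.05. The Il6 change was larger in Balb/c, with an interaction of 2.88 ± 0.30 (log2 ± SE, adjusted p = 0.00609). Its mean was 6.52 ± 0.20 in Balb/c sham and 9.48 ± 0.01 in Balb/c irradiated arrays (SD, n = 3). In C57BL/6 it was 9.35 ± 0.47 and 9.43 ± 0.22. The interferon-induced Ifi44l was at 2.19 ± 0.20, with C57BL/6 sham values near the bottom of the scale at 2.29 ± 0.06. Ly6e, a membrane protein, was at 2.47 ± 0.31 and Chsy1, a chondroitin synthase, at 1.15 ± 0.17. Mcm5 was lower in the interaction, at -1.77 ± 0.20, as were Oasl2, at -1.82 ± 0.24, and D630023F18Rik, at -4.42 ± 0.59. Means of D630023F18Rik and Oasl2 in sham arrays were near the bottom of the scale, at 2.23 ± 0.00 and 3.14 ± 0.40 in C57BL/6 and 2.23 ± 0.00 and 2.23 ± 0.00 in Balb/c. The sizes given for these 2 genes and Ifi44l depend on the background correction and are rough. Not passing were Lrba at 1.77 ± 0.29 (adjusted p = 0.0822) and Cdk1 at -1.93 ± 0.32 (adjusted p = 0.0857). Mki67 did not pass at -2.28 ± 0.37 (adjusted p = 0.0822), nor did Apoe at -1.79 ± 0.41 (adjusted p = 0.235) and Cdkn1a at -1.23 ± 0.29 (adjusted p = 0.279). Chsy1 lost its call without each of 11 arrays in turn, at adjusted p up to 0.185 without Balb/c sham replicate 1, and Ly6e did so without each of 7 arrays in turn, at adjusted p up to 0.0697 without Balb/c sham replicate 2. D630023F18Rik did so without each of 10 arrays in turn, at adjusted p up to 0.0925 without Balb/c sham replicate 1, and Mcm5 did so without Balb/c sham replicate 1 (adjusted p = 0.0577). Oasl2 did so without each of 9 arrays in turn, at adjusted p up to 0.0925 without Balb/c sham replicate 1. Chsy1, D630023F18Rik and Oasl2 also lost theirs with the 18S covariate, at adjusted p from 0.0777 to 0.0973. The count was 3 without C57BL/6 sham replicate 1, 4 without C57BL/6 sham replicate 2, 3 without C57BL/6 irradiated replicate 3, 2 without Balb/c sham replicate 1, 3 without Balb/c sham replicate 2 and 4 without Balb/c irradiated replicate 3. It was 2 with no filter, 3 with the 3' minus 5' covariate and 2 without both arrays that stood apart.

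Among the lists, the interaction was negative for cell cycle genes, 1 of 17 called lower and 12 adjusted over the list alone. They had a median interaction of -1.41 (adjusted p = 2.44e-16, and adjusted p = 0.0512 with an estimated correlation). MHC class I genes had a median interaction of -0.39 (adjusted p = 0.0072, and adjusted p = 0.528 with an estimated correlation). Activated microglia genes, 0 of 24 called and 1 higher and 2 lower adjusted over the list alone, had a median interaction of -0.33 (adjusted p = 0.00461, and adjusted p = 0.673 with an estimated correlation). Lysosomal genes had a median interaction of -0.17 (adjusted p = 0.00137, and adjusted p = 0.528 with an estimated correlation). Oxidative phosphorylation genes had a median interaction of -0.17 (adjusted p = 0.0137, and adjusted p = 0.78 with an estimated correlation). Positive median interactions were found for interferon-induced genes and neutrophil markers. Interferon-induced genes, 0 of 24 called higher and 1 lower (Oasl2), had a median interaction of 0.48 (adjusted p = 0.00706, and adjusted p = 0.528 with an estimated correlation). Neutrophil markers, 0 of 4 called higher and 0 lower, and 2 higher and 0 lower adjusted over the list alone, had a median interaction of 3.68 (adjusted p = 0.00137, and adjusted p = 0.528 with an estimated correlation). That value was 2.15 without C57BL/6 sham replicate 1, whose neutrophil score was 2.61 against -0.65 and -1.09 in the other C57BL/6 sham arrays. Balb/c irradiated replicate 3 had a score of -0.43 against 2.09 and 2.70 in its group. S100a8 and S100a9 did not pass, at 3.89 ± 0.95 and 2.72 ± 0.91. The interferon list lost its call without C57BL/6 irradiated replicate 1 (adjusted p = 0.0875). The oxidative phosphorylation list lost it without C57BL/6 sham replicate 2, C57BL/6 irradiated replicate 3 and Balb/c irradiated replicate 2 (adjusted p up to 0.408, without C57BL/6 irradiated replicate 3) and with array weights (adjusted p = 0.0584). The MHC class I, activated microglia and oxidative phosphorylation lists lost theirs with either covariate or without both arrays that stood apart, at adjusted p up to 0.235, 0.232 and 0.919. The lysosome list lost its call with the 3' minus 5' covariate (adjusted p = 0.088), the interferon list with the 18S covariate (adjusted p = 0.0766) and the neutrophil list with no filter (adjusted p = 0.071). The activated microglia median was -0.19 without Balb/c irradiated replicate 2. The lysosome median was -0.11 without C57BL/6 irradiated replicate 2. The oxidative phosphorylation median was -0.26 without C57BL/6 sham replicate 1, -0.11 without C57BL/6 sham replicate 2, -0.11 without C57BL/6 irradiated replicate 3, -0.07 without Balb/c irradiated replicate 2 and -0.26 without Balb/c irradiated replicate 3. None of these 7 lists held with an estimated correlation. Of the lists without a call in the interaction, some were called under alternatives: astrocyte under 8 alternatives (adjusted p down to 8.89e-05 without both arrays that stood apart), endothelial under 6 alternatives (down to 0.00442 without Balb/c sham replicate 3), oligodendrocyte under 3 alternatives (down to 0.00142 without C57BL/6 irradiated replicate 1) and oxidative stress under 3 alternatives (down to 0.0344 without Balb/c irradiated replicate 1). So were monocyte under 2 alternatives (adjusted p down to 0.00232 without C57BL/6 sham replicate 3), border-associated macrophage under 1 alternative (0.0147 without C57BL/6 sham replicate 3), neuron under 1 alternative (0.0195 without Balb/c irradiated replicate 3), MHC class II under 1 alternative (0.0288 without Balb/c sham replicate 2) and immediate early under 1 alternative (0.0385 without both arrays that stood apart).

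The strains differed without irradiation. Ccr6, a chemokine receptor, was higher in Balb/c sham, at 11.85 ± 0.04 against 3.22 ± 0.30, near the bottom of the scale (log2 mean ± SD, n = 3, adjusted p = 1.69e-10). Trim30d was at 2.41 ± 0.23 in Balb/c, near the bottom of the scale, and at 10.69 ± 0.15 in C57BL/6. Trim12a, Trim5 and Trim34a, members of the same gene family, were lower in Balb/c as well, at -6.38 ± 0.11, -5.40 ± 0.23 and -6.56 ± 0.18 (log2 ± SE). The other large rises were Qpct (6.86), Pdxdc1 (6.83), Tafa2 (6.16), Ifi202b (6.05), Tmem87a (5.87), Msh5 (5.87), Cap1 (5.36), Ifi44l (5.25) and Zfp458 (5.11), with adjusted p from 1.69e-10 to 2.82e-04 for all 10. The other large falls were Upk1b (-6.76), G530011O06Rik (-6.52), Gm10033 (-5.60), Vps52 (-5.27), Nxpe4 (-4.94) and Spint1 (-4.77), with adjusted p from 6.29e-11 to 1.39e-06 for all 10. Sham arrays of the strains did not overlap for these 20 genes, as the rule for naming required, and all 20 kept their calls without each array in turn. For 19 of them the mean of the lower strain was under 5, so the sizes depend on the background correction and are rough. In all, 954 genes were called, 476 higher and 478 lower in Balb/c, with 218 higher and 254 lower by at least 2-fold and 2077 at an unadjusted p under 0.05. A probe can also read a base difference between strains. With all probe sets tested as they are 1609 were called, and among genes with at least 2 kept probe sets that all went one way 253 were called.

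Cell cycle genes were higher in Balb/c sham arrays, 8 of 17 called higher and 1 lower, with 2.71 ± 0.45 for Rrm2, 1.61 ± 0.26 for Mki67 and 1.10 ± 0.19 for Cenpa. They had a median difference of 1.01 (adjusted p = 6.39e-04, and adjusted p = 0.508 with an estimated correlation). Lysosomal genes had a median difference of 0.22 (adjusted p = 0.002, and adjusted p = 0.508 with an estimated correlation). Interferon-induced genes were lower in Balb/c, 10 of 24 called, with -3.72 ± 0.37 for Bst2, -2.03 ± 0.32 for Ifit3 and -1.51 ± 0.19 for Trim30a. That list had a median difference of -0.70 (adjusted p = 4.52e-11, and adjusted p = 0.0717 with an estimated correlation). MHC class II genes had a median difference of -0.69 (adjusted p = 0.0086, and adjusted p = 0.508 with an estimated correlation). MHC class I genes had a median difference of -0.21 (adjusted p = 0.0126, and adjusted p = 0.508 with an estimated correlation). Border-associated macrophage markers had a median difference of -0.57 (adjusted p = 0.002, and adjusted p = 0.592 with an estimated correlation). Neutrophil markers had a median difference of -2.20 (adjusted p = 0.0297, and adjusted p = 0.592 with an estimated correlation). Slc2a5, a fructose transporter, was at -3.41 ± 0.13 and Fcrls, a microglial marker, at -1.26 ± 0.12. Il6 was lower, at -2.83 ± 0.21, while Cdkn1a and Apoe were higher, at 1.61 ± 0.21 and 1.35 ± 0.29. H2-D1 was at -2.16 ± 0.45 on its brightest probe set and at 1.13 on the mean of its probe sets (adjusted p = 0.0328). The same sham arrays enter this contrast and the interaction, so they share chance values. With the mean of all probe sets per gene 3 of the 7 lists were called, and cell cycle (adjusted p = 0.124), lysosome (adjusted p = 0.0612), MHC class I (adjusted p = 0.461) and neutrophil (adjusted p = 0.0612) were not. MHC class I also lost its call with a filter at 7 (adjusted p = 0.0782), and neutrophil with no filter (adjusted p = 0.0659) and with array weights (adjusted p = 0.0608). The border-associated macrophage list lost its call without C57BL/6 sham replicate 3 (adjusted p = 0.103) and the neutrophil list without C57BL/6 sham replicate 1 (adjusted p = 0.167). The neutrophil difference was -0.96 without C57BL/6 sham replicate 1. The border-associated macrophage difference was -0.89 without C57BL/6 sham replicate 2 and -0.36 without C57BL/6 sham replicate 3. The MHC class II difference was -1.24 without C57BL/6 sham replicate 2, -0.32 without C57BL/6 sham replicate 3 and -0.30 without Balb/c sham replicate 2. Cholesterol and lipid handling, not called (adjusted p = 0.0708), was called under 3 alternatives (adjusted p down to 0.00938 with no filter). Median, mean and test also differed in sign for lists without a call: neutrophil in C57BL/6, and oxidative stress and neuron in Balb/c. They did so for p53 targets, inflammatory cytokines and immature neurons in the interaction, and for activated microglia, complement, immature neurons and oligodendrocytes between the strains.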

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

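The test of dim values, the 18S covariate and the splits with additive effects taken out in this part were chosen after the results were seen. In the interaction, the change in Balb/c minus that in C57BL/6, Ifi44l was at 2.19, Il6 at 2.88, Ly6e at 2.47 and Chsy1 at 1.15 on the log2 scale, each called. Mcm5 was at -1.77, Oasl2 at -1.82 and D630023F18Rik at -4.42, each called. Group means of Ifi44l, Oasl2 and D630023F18Rik lay near the bottom of the scale, so their sizes depend on the background correction and are rough. Lists called in the interaction at the preset correlation, none of them with an estimated one (adjusted p from 0.0512 to 0.78), had median differences of -1.41 for cell cycle, 3.68 for neutrophil, 0.48 for type I interferon response, -0.17 for lysosome, -0.33 for activated or primed microglia, -0.39 for MHC class I and -0.17 for oxidative phosphorylation. Of 2190 probe sets tested that the annotation does not name, 96 were higher and 79 lower after irradiation averaged over strains. For the 7 genes of the interaction 2 of 100 splits gave as many, the real one included. This count says little, since other splits exchange strain labels within a treatment and so put the strain difference into the spread between arrays. The highest other split gave 1576, which measures the strain difference and points to that structure of the samples. With the additive effects of strain and irradiation taken out of each gene, 2 of 100 splits gave 7 or more, the real one included. So large a count was rare among the splits, but another split gave 8, more than the real one, and chance is not excluded. For the lists of the interaction chance cannot be excluded, since 31 of 100 splits gave 7 or more, up to 11 in another split, and 26 of 100, up to 12, with these effects taken out.

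Cell cycle genes were higher after irradiation in C57BL/6 but not called so in Balb/c, and their sham scores differed, at -0.85 ± 0.30 in C57BL/6 and 0.10 ± 0.12 in Balb/c against 0.64 ± 0.15 and 0.11 ± 0.21 after irradiation (SD, n = 3). The tables argue against 1 array as the source, as the highest median interaction without any 1 array was -1.30. They also argue against the 3' minus 5' difference, as the median was -1.34 with that covariate (-1.41 without). With the 18S covariate the median was -1.35. This cannot decide on the 18S signal, which was lower in every irradiated array than in every sham array. The list's interaction was at an adjusted p of 0.0512 with an estimated correlation. Dim values cannot be told apart from a difference in response: the 6 members with a mean above 8 had a median of -0.57 (mean -0.73 ± 0.29 SE, 5 negative) and the 11 dimmer ones -1.93. Only 17 of the 37 members on the array passed the filter, which high values in 1 group of 3 arrays alone can meet. In sham mice 8 of 17 members were called higher and 1 lower in Balb/c (adjusted p = 6.39e-04 for the list, and adjusted p = 0.508 with an estimated correlation), and the list was not called with the mean of all probe sets (adjusted p = 0.124). A strain difference in cell cycle genes of the sorted CD11b+ cells stays open, and cell division was not measured.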

How the results depend on the processing

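The alternatives without the 2 arrays that stood apart and with the 18S signal as a covariate were chosen after the data were seen. Of 541 named gene and contrast pairs 269 were called, and 186 of these kept their calls without each array in turn. Of 14789 values under alternatives, 943 no longer passed the threshold, 204 came to pass it and 1 reversed: H2-D1 between strains was -2.16 and 1.13 with the mean of its probe sets, and the cause was not tested. All called lists kept their direction under quantile normalization and centring, and under these 2 no split of calls moved by over 10 percentage points. These 2 say little about other normalizations, since the deposited arrays already had the same sorted values. A fit of the compared groups alone gives no value for the average and the interaction, which use all 4 groups. Signal over background limits what is measured near the lowest value, 2.23, as 55.1% of probe set values were under 3.

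Counts of called genes, main values 335 in C57BL/6, 561 in Balb/c, 1447 in the average, 7 in the interaction and 954 between strains, moved as follows. With no filter they were 155, 283, 867 and 2 for the first 4. A fit of the compared groups alone gave 96 in C57BL/6 and 364 in Balb/c. An adjusted p under 0.10 gave 725, 1076 and, for the interaction, 11. A 2-fold minimum gave 179, 249, 312 and, between strains, 472. The 3' minus 5' covariate gave 104 in Balb/c, 873 in the average and 3 in the interaction, and the 18S covariate 39 in Balb/c and 241 in the average. As the 18S signal was lower in every irradiated array than in every sham array, its covariate cannot tell it apart from irradiation. Without both arrays that stood apart the values were 104 in C57BL/6, 361 in Balb/c, 788 in the average and 2 in the interaction. All probe sets as they are gave 1609 between strains, and genes with at least 2 probe sets that go one way 253. With no filter 18193 genes entered the adjustment, and fewer arrays entered the fits of the compared groups and of left-out arrays; for the rest the cause was not tested. Leaving out each array in turn gave 113 to 351 in C57BL/6, 218 to 592 in Balb/c, 923 to 1455 in the average, 2 to 8 in the interaction and 681 to 939 between strains.

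The 22 lists tested gave 17, 12, 17, 7 and 7 calls in the same order. These came to 3, 2, 2, 0 and 0 with an estimated correlation, to 9 in C57BL/6 and 1 in the interaction with fry, to 4 in the interaction with either covariate and to 3 between strains with the mean of probe sets. Leaving out each array gave 16 to 17, 9 to 15, 14 to 17, 6 to 10 and 6 to 8. The correlation between strains, 0.635, kept its direction under all alternatives, was 0.771 with the 18S covariate and ranged from 0.543 to 0.678 without each array.

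The samples share only a replicate number. Deviations of same-numbered arrays correlated from -0.0178 to 0.114 in C57BL/6, from 0.0611 to 0.283 in Balb/c and from -0.0478 to 0.0651 between sham groups, and not every array correlated best with its own number. The replicate block gave 217 in C57BL/6, 371 in Balb/c, 1 in the interaction and none of its 7 (adjusted p from 0.0691 to 0.295), 1072 in the average and 947 between strains.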

Other observations

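The test of the share of microglia, the test over 77 cilium genes, the binomial test and the 18S covariate were chosen after the results were seen. Genes of motile cilia stood among the largest changes of the average, chosen after their values were seen: Ccdc153 (2.32), Dynlrb2 (2.27), Hoatz (2.21), Rsph1 (4.59-fold), Capsl (2.08), Cfap54 (1.99), Tmem212 (1.79) and Tmem107 (1.77). Of 91 further motile cilium and ependymal genes, written before their values were seen, 77 were on the array and 11 passed the filter on dim values, which high values in irradiated arrays alone can meet. Over all 77, dim ones included, the median was 0.05 in the average and the mean 0.31, with 68 above 0 and 1 called. Their score was 0.314 higher after irradiation (exact permutation test, two-sided, p = 0.01). With genes under the filter included, none of the 77 was called in either strain. Among the 11 that passed the filter, 0 were called in C57BL/6, 2 higher in Balb/c and 3 higher in the average, and 0 lower. Other genes called in both strains and outside the lists, chosen after their values were seen, were Pqlc3 (2.72), Ms4a4c (2.60), Cd72 (2.55), Ephx1 (2.21), Gpr65 (2.06), Anxa2 (1.52), Lgals1 (1.42), Vim (1.38) and Timp3 (1.51), and lower Myc (-1.21), Cebpa (-1.28), Batf3 (-1.03) and Irf5 (-0.92). After irradiation 818 genes were called between the strains, 517 of them also in sham and 515 in the same direction, with r = 0.752 across genes, which are not independent replicates.

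Astrocyte markers were higher after irradiation as a list in both strains, although the cells were sorted on CD11b. In C57BL/6 1 of 12 was called and in Balb/c 5, and neither list held with an estimated correlation (adjusted p = 0.273 and adjusted p = 0.204, in the average adjusted p = 0.179). A lower share of microglia that raises all other cells alike was examined with lists picked after their changes were seen, so the test cannot decide it. The astrocyte score rose by 0.821 more than the mean of the oligodendrocyte and neuron scores (exact permutation test, two-sided, p = 0.005, the smallest the 400 permutations can give). Endothelial and pericyte markers rose too, by 0.683 (exact permutation test, p = 0.005), and with their score in that mean the astrocyte score still rose by 0.601 more (exact permutation test, p = 0.005). In C57BL/6 irradiated replicate 1 the neuron and oligodendrocyte scores, 0.52 and 0.27, exceeded that of astrocytes, 0.16, so the difference did not hold in every array. The tables argue against the 3' minus 5' difference as the source, as the list's median was 0.92 with it as a covariate and 0.78 without. With the 18S covariate the median was 1.25. This cannot decide on the 18S signal, which was lower in every irradiated array than in every sham array. A candidate explanation is more astrocyte RNA in the sorted samples, since 21 astrocyte genes outside the list had a median change of 0.78, 20 of them above 0 and 11 called higher, though Glul, the brightest at 13.7, was at -0.09. Whether astrocytes themselves changed stays open and was not tested.

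Base differences under the probes and strain differences in expression in sham mice cannot be told apart for a part of the calls. Of 314 calls with other probe sets, 169 (53.8%) had all of these change the same way at an unadjusted p under 0.05, against 62.1% of 285 irradiation calls (Fisher's exact test p = 0.0468), so more than 1 probe set measured these 169. Of the 145 others 77 (53.1%) were lower in Balb/c, where base differences would make most lower (exact binomial test, two-sided, p = 0.507), against 60.2% of 108 for irradiation. Inherited blocks of neighbouring genes, the other explanation, cannot be told apart from common clustering of changed genes: 157 neighbouring pairs were called between strains, against 99.1 by shuffling (permutation p = 0.001, the smallest that 1000 shuffles can give), a ratio of 1.58, and irradiation calls had a ratio of 1.85. Trim12a, Trim5, Trim34a and Trim30d lie close together, with 0 to 14 genes between them.

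With 10 splits of 3 against 3 arrays the share is never under 0.05, so only the values are given. In C57BL/6 335 genes were called and at most 1 in another split, and 17 lists against 13. In Balb/c 561 genes and 12 lists were called, against at most 0 and 15. Between strains 954 genes and 7 lists were called, against at most 0 and 8. As many or more were given by 1, 1, 1, 3, 1 and 2 splits in this order of genes and lists, the real one included. For the gene count of the average chance can be excluded, as 1447 genes came in 1 of 100 splits, the highest other 14. For its list count chance is not excluded: 3 of 100 splits gave 17 or more, and another split gave 18. For the correlation of 0.635, 1 of 100 splits, the real one, gave a value as high. So high a correlation was rare among the splits, but another split came close, at 0.588, and chance is not excluded.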
